A study of Rattus norvegicus with 18 samples.

How the data were processed

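RNA, 5-hydroxymethylcytosine and input DNA were each sequenced in 3 control and 3 vitamin C samples of primary rat Schwann cells at passage 3, per the labels, 18 libraries in all. Total RNA depleted of ribosomal RNA was sequenced. Genomic DNA was sequenced after immunoprecipitation of 5-hydroxymethylcytosine (hMeDIP, with an Active Motif kit) and without precipitation as input. Each sample's group and number came from its own labels. The labels do not say that samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

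The authors deposited whole-number counts of reads per gene for the RNA libraries and per peak for the hMeDIP and input libraries, with a list of 215951 peaks that gives each peak's position, gene and genomic feature. The submitters' processing notes name CASAVA 1.4, Trim Galore, STAR, BWA and HTSeq, without saying which step each one did. The genome build, the gene annotation release, the peak caller, the rule that merged peaks, the strand setting of counting and the base convention of positions are not given in the sources used here. Positions are therefore printed as the peak list gives them, and RNA from overlapping or antisense genes and from near-identical gene copies cannot be told apart in these counts. Gene symbols came from the peak list, which names 17003 of the 32883 RNA identifiers, so genes without a peak have an identifier but no symbol here.

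Between 23381814 and 33173282 reads per RNA library were counted in genes. Entries that name no gene (reads outside genes, ambiguous reads and reads aligned at several places) held 42.3% to 53.9% of the counted RNA reads and were left out of library sizes and tests. Of all counted RNA reads, those aligned at several places were 44.9% in vitamin C replicate 1, against 34.4% and 32.7% in the other treated libraries and 36.5% to 42.5% in the controls. Each hMeDIP library had 24020306 to 39899445 reads in peaks and each input library 7201638 to 9521037. Reads outside peaks were 56.1% to 69.2% of hMeDIP reads and 91.3% to 91.6% of input reads. No molecular identifiers are mentioned, so reads are not known to be independent molecules.

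Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM factors, the default expression filter and Benjamini-Hochberg adjustment at 0.05, treatment being the only term. The RNA, hMeDIP and input libraries were fitted apart. A further fit over hMeDIP and input libraries with a term per sample tested whether enrichment over input changed. Levels are CPM of the reads in genes or peaks, scaled by TMM factors, as mean ± SD over 3 libraries. Changes are log2 fold changes, vitamin C over control, with the standard error of the fit. TMM scaling removes a change shared by most peaks, so the total of hMeDIP reads in peaks relative to input was compared by an exact permutation test, as a ratio that also depends on sequencing depth. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists, with an estimated correlation and the fry test as alternatives. The Spearman correlation of RNA and hMeDIP changes across genes was tested with 100000 permutations, two-sided. Overlaps and genomic features were tested with Fisher's exact test, two-sided. Other tools were DESeq2 1.42.0, data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

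Before the data were examined, 19 gene lists, 10 lists of cell type markers, the tests and the rule for naming genes were fixed. The rule took the 10 highest and 10 lowest changes among RNA genes past the threshold with an average log2 CPM of at least 3, a proper symbol and no overlap between groups. It added up to 4 members past the threshold per list, a fixed set of Schwann cell, TET and vitamin C transport genes, the 5 peaks of smallest p in each direction, the best peak of 6 myelin genes, and 10 genes called in RNA that hold a called peak. Some genes of the rule were left out for length, and some are not reported here. Mal, Cnp, Fig4, Il33 and the genes named from the 4 later lists fall outside it and were chosen after their values were seen. For RNA identifiers without a symbol, 2 that rose and 2 that fell were named. Alternatives were other scaling factors, DESeq2, other filters, the replicate number as a block, leaving out each replicate in turn, and other set tests and gene-level summaries. Scaling by all counted reads, the share of all counted reads in peaks, a comparison of each list's median with random gene lists matched on mean expression, a fit on 2 against 2 hMeDIP libraries and 4 more gene lists were chosen after the data were seen.

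Replicate numbers shared by both groups are not said to pair samples, and were not used in the fits that give the main values. Counts of hMeDIP replicates 1 and 3 over peaks differed by no more than sampling noise in both groups (chi-square per degree of freedom 0.963 in controls and 0.896 in treated libraries). Other pairs within a group reached 1.08 to 1.47. All pairs of input libraries were at 0.974 to 0.992, within groups and across them. The share of reads in peaks, however, differed between replicates 1 and 3 (31.7% and 35.7% in controls, 41.4% and 40.8% in treated libraries, with counting errors of 0.0071 and 0.0073 points). They were therefore kept as separate libraries, and the test was also run with the pair of each group summed. This difference does not show that they came from separate cultures. Within groups, hMeDIP pairs lay at 0.896 to 1.47 per degree of freedom, near sampling noise, against 5.27 to 41.0 in RNA. The hMeDIP p-values therefore measure little beyond sampling noise of reads.

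The RNA, hMeDIP and input fits were each checked on simulated counts with 200 changed features, raised and lowered in equal number. Far fewer features changed there than passed in the data (40.1% of genes and 75.4% of hMeDIP peaks). TMM scaling was therefore not checked at that extent of change. The fit of hMeDIP over input and the permutation and Fisher tests were not checked. In RNA, over 12815 genes, 53.7%, 91.0% and 96.9% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 6.98% of calls were false. In hMeDIP, over 20000 peaks, 10.4%, 73.1% and 100% of peaks changed by 0.25, 0.5 and 1 were recovered, and 8.96% of calls were false, so both shares of false calls lay above the nominal 5%. In input, over 19969 peaks, the shares recovered at the same sizes were 0%, 7.46% and 78.5%. The list test called the 1 shifted list and 0 of the others among 21.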

Results

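Schwann cells are the glia that wrap and myelinate the axons of peripheral nerves, and in culture they depend on vitamin C (ascorbate) to build a basal lamina and to myelinate. Primary rat Schwann cells at passage 3 were compared with and without vitamin C to ask how the vitamin acts on myelin-related genes and on DNA demethylation. RNA was sequenced in 3 control and 3 treated samples, with 23381814 to 33173282 reads in genes per library. DNA carrying 5-hydroxymethylcytosine, the product of TET enzymes acting on methylated cytosine, was measured by hMeDIP in 3 and 3 libraries with 24020306 to 39899445 reads in peaks. Input DNA of the same samples had 7201638 to 9521037 reads in peaks. Errors of log2 changes are SE and errors of levels are SD, with n = 3 per group throughout.

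In RNA, genes of the extracellular matrix rose with vitamin C, whereas myelin genes went both ways. Of the fibrillar and microfibril matrix list, 15 of 21 tested genes rose and 0 fell (15 and 0 adjusted over the list alone), with a median change of 1.26. The fibrillar collagen Col1a1 rose by 1.16 ± 0.07, Col5a2 by 1.26 ± 0.05 (from 932 ± 15.0 to 2234 ± 69.0 CPM), Col5a3 by 1.89 ± 0.09 and the matrix protein Postn by 2.95 ± 0.19. This list stood above other genes in limma's camera test (adjusted p = 1.58e-21), also with an estimated correlation (adjusted p = 0.0226). Of the basal lamina and receptor list, 14 of 20 rose and 1 fell (14 and 1 adjusted over the list alone). Among them Itgb4, the beta subunit of a laminin receptor, rose from 102 ± 1.32 to 401 ± 10.4 CPM, and Nid2 and Col4a1, components of basement membranes, rose by 1.32 ± 0.06 and 1.05 ± 0.06 on the log2 scale. The list passed camera in limma (adjusted p = 1.57e-12) but had an adjusted p = 0.121 with an estimated correlation. Of 15 genes that modify and fold collagen, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera in limma, adjusted p = 0.00189, and adjusted p = 0.425 with an estimated correlation). The median of this list did not pass against lists matched on mean expression (adjusted p = 0.060). Genes that rose included Adamts2, which trims procollagen (2.40 ± 0.08), and Serpinh1, a collagen chaperone (0.57 ± 0.06).

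Markers of pericytes and smooth muscle moved with the matrix genes. Of 5 tested, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera in limma, adjusted p = 9.15e-09, and adjusted p = 0.0410 with an estimated correlation). Among them were Tagln (from 11.9 ± 0.463 to 57.0 ± 5.94 CPM), Des (from 13.0 ± 1.33 to 37.9 ± 2.08 CPM) and Pdgfrb (1.11 ± 0.06). The markers Rgs5, Cnn1, Acta2 and Notch3 of this list had 0 to 10 reads per library and were not tested. Of 4 fibroblast markers, Col1a1 rose and Gsn (-0.75 ± 0.07), Pdgfra (-1.38 ± 0.24) and Pi16 (-0.78 ± 0.15) fell, the same counts adjusted over the list alone (camera in limma, adjusted p = 0.573, and adjusted p = 0.0234 for the median against lists matched on mean expression). Of 4 perineurial markers, Itgb4 and Ntn4 rose and Sfrp4 and Slc2a1 fell, adjusted over the list alone too (camera in limma, adjusted p = 0.449). Of 37 skeletal muscle genes, a list written after the RNA values were seen, 33 rose and 0 fell, with a median of 1.60 (camera in limma, p = 1.10e-23, and p = 0.0147 with an estimated correlation). Neither of the 2 tested macrophage markers passed, and the 1 endothelial marker tested, Tek, rose by 1.15 ± 0.19. Of lymphocytes, erythroid cells and adipocytes, 0 markers had a symbol and enough reads to be tested. Markers of fibroblasts, macrophages, endothelium, neurons and perineurium that were left untested for few reads had at most 12 reads in any library. Of 5 neuron markers Tubb3 rose and Nefl and Gap43 fell (1 and 2 adjusted over the list alone; adjusted p = 0.675 in limma's camera), and the call of Gap43 was lost in DESeq2 and on leaving out any control or vitamin C replicate 3.

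Of 17 tested genes for myelin proteins and lipid enzymes, 6 rose and 4 fell (6 and 5 adjusted over the list alone). The largest rise was in Gldn, a protein that assembles sodium channels at nodes of Ranvier, from 1.67 ± 0.227 to 23.2 ± 2.84 CPM (3.81 ± 0.14). The myelin proteins Mbp and Pmp22 rose by 0.77 ± 0.05 and 0.49 ± 0.08, and Pmp2, a lipid carrier of peripheral myelin, fell by 0.73. Cnp and Fig4 fell by 0.40 and 0.28, and Mal, a membrane protein of myelin, fell from 0.821 ± 0.232 to 0.0858 ± 0.0200 CPM. As a set the myelin list did not pass (camera in limma, adjusted p = 0.165). Of 18 promyelinating transcription factors and signalling genes, 7 rose and 4 fell, the same adjusted over the list alone. The list had an adjusted p = 0.0695 in limma's camera, and 0.0360 to 0.0945 over left-out libraries. It passed without vitamin C replicate 1 or 3, and with the replicate block (adjusted p = 0.0368 in limma's camera). Egr2, the transcription factor that drives myelination, rose from 2.09 ± 0.375 to 6.76 ± 0.761 CPM, Zeb2 rose by 1.60 ± 0.09, and Pou3f1, a factor of the promyelinating stage, fell by 0.81. Sox10, which specifies the lineage, differed by 0.12 ± 0.05 (edgeR, adjusted p = 0.102) and passed without vitamin C replicate 1.

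Genes of immature and repair Schwann cells rose more often than they fell, 10 against 4 of 18 (10 and 4 adjusted over the list alone; camera in limma, adjusted p = 2.69e-04, and adjusted p = 0.269 with an estimated correlation). Those that rose included L1cam, an adhesion molecule (1.32 ± 0.06), Gdnf, a trophic factor (1.46 ± 0.07), Gfap (0.96 ± 0.05) and Fgf5 (1.12 ± 0.06). The 4 that fell included Gap43, a call lost in DESeq2 and on leaving out any control or vitamin C replicate 3. Jun, the transcription factor of the repair state, rose by 0.22 ± 0.07 (edgeR, adjusted p = 0.0377), a call lost under library-size scaling and on leaving out any library except vitamin C replicate 1. Of 8 Schwann cell markers, Cdh19 (0.67 ± 0.09) and Gas7 (0.30 ± 0.06) rose and S100b (from 1173 ± 42.4 to 589.7 ± 36.4 CPM) and Erbb3 (-0.16 ± 0.05) fell, the same adjusted over the list alone (camera in limma, adjusted p = 0.765). The call of Erbb3 was lost on leaving out any library except vitamin C replicate 1.

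**Figure D1:**
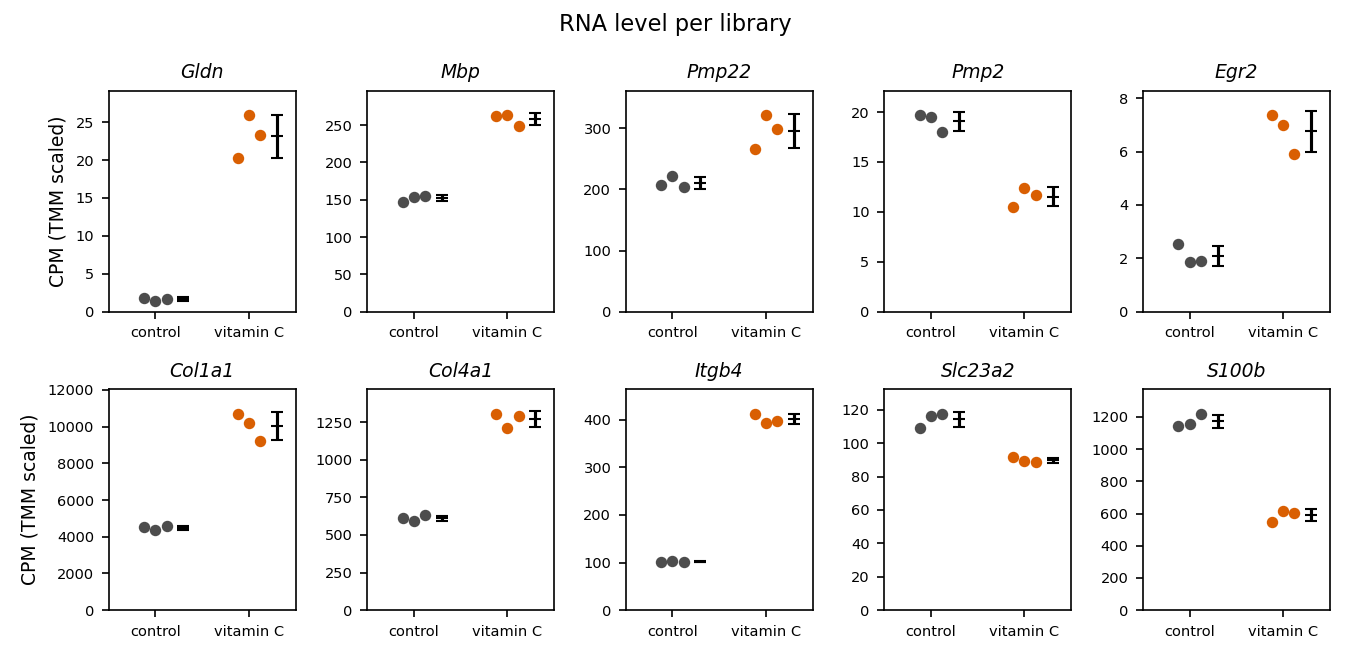
RNA level in TMM-scaled CPM of 10 genes in each library (points, 3 control and 3 vitamin C), with the mean and SD as a bar beside them. Itgb4 lies at 102 ± 1.32 CPM in controls and 401 ± 10.4 CPM with vitamin C, and S100b falls from 1173 ± 42.4 to 589.7 ± 36.4 CPM.

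Immediate early genes, which respond to growth signals, rose in 8 of 12 cases and fell in 1 (8 and 2 adjusted over the list alone; camera in limma, adjusted p = 0.00189, and adjusted p = 0.132 with an estimated correlation). Egr1 rose by 2.53 ± 0.16 and Nr4a1 by 1.27 ± 0.08. Of 19 genes for axon guidance and adhesion, 9 rose and 4 fell (10 and 4 adjusted over the list alone; camera in limma, adjusted p = 4.45e-04, and adjusted p = 0.425 with an estimated correlation). The semaphorin receptor Nrp2 rose by 2.31 ± 0.06 and the semaphorin Sema4f by 1.65 ± 0.07. Of 20 targets of the hypoxia factor HIF, whose degradation needs hydroxylases that use ascorbate, 10 fell and 3 rose (10 and 3 adjusted over the list alone; camera in limma, adjusted p = 0.109). With an estimated correlation camera gave this list an adjusted p = 0.457. The median of these targets passed against random lists matched on mean expression (adjusted p = 0.0024), a test chosen after the data were seen. That test draws genes singly and does not allow for correlation between them. Ndrg1 fell by 0.93 and Adm by 1.32, while Vegfa rose by 1.05. Of 16 antioxidant genes 7 fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.283 in limma's camera). Gpx1 changed by -0.96 ± 0.08, Cat, the gene for catalase, by -0.74 ± 0.05 and the cystine transporter Slc7a11 by 3.59 ± 0.16. Of 8 genes for vitamin C uptake and recycling, 4 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.109 in limma's camera). The ascorbate transporter Slc23a2 fell by 0.35 (from 114 ± 4.48 to 89.8 ± 1.52 CPM).

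Of 14 genes of cytosine oxidation and DNA methylation, 2 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.494 in limma's camera). Tet3 rose by 0.45 ± 0.15 (edgeR, adjusted p = 0.0378), a call lost on leaving out any of the controls. Tet1 and Tet2 differed by 0.18 ± 0.13 and 0.15 ± 0.11 without passing (edgeR, adjusted p = 0.303 and 0.298). Idh1 and Idh2, enzymes that supply the co-substrate of TET enzymes, fell by 0.69 and 0.40. Of 16 JmjC histone demethylases 1 passed, Kdm2b (-0.21 ± 0.06), whose call was lost in DESeq2 and without control replicate 2 or 3 or vitamin C replicate 2, and none did adjusted over the list alone (adjusted p = 0.876 in limma's camera).

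Sterol synthesis genes rose in 10 of 20 cases and fell in 3 (10 and 3 adjusted over the list alone; camera in limma, adjusted p = 0.197). Of 15 fatty acid synthesis genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.349 in limma's camera). The desaturase Scd2 changed by -0.55 ± 0.07. Of 13 genes of the unfolded protein response 5 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.109 in limma's camera, and 0.0398 to 0.191 over left-out libraries), and the list passed without vitamin C replicate 1. Trib3 and Chac1 each rose by 1.43. Of 10 proliferation genes Mcm6 and Aurka fell (1 lower adjusted over the list alone; adjusted p = 0.675 in limma's camera), and the call of Aurka was lost in DESeq2 and without control replicate 1 or 2 or vitamin C replicate 2 or 3. Of 9 interferon response genes, Ifit2 (0.37 ± 0.10) and Ifi44 (0.26 ± 0.08) rose and Mx1 and Mx2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.109 in limma's camera). Mx1 had 0.656 ± 0.0726 CPM in controls and 0 reads in each treated library. The call of Ifit2 was lost without vitamin C replicate 2. That of Ifi44 was lost in DESeq2, under library-size scaling, with the replicate block and on leaving out any library except vitamin C replicate 1. Cytokines and chemokines changed in 7 of 8 cases, 4 higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.193 in limma's camera). The chemokine Ccl2 fell by 3.11, Il33 by 3.00, Il11 by 2.33 and the interferon-induced Mx2 by 2.43, while the chemokine Cxcl1 rose from 0.294 ± 0.0622 to 3.21 ± 0.218 CPM (3.43 ± 0.21) and Cxcl12 rose by 0.80. For the lists of myelin, cytosine oxidation, JmjC, antioxidant and cytokine genes and of Schwann and perineurial markers, none of them past the threshold, the median, mean and direction of the test differed in sign.

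**Figure D2:**
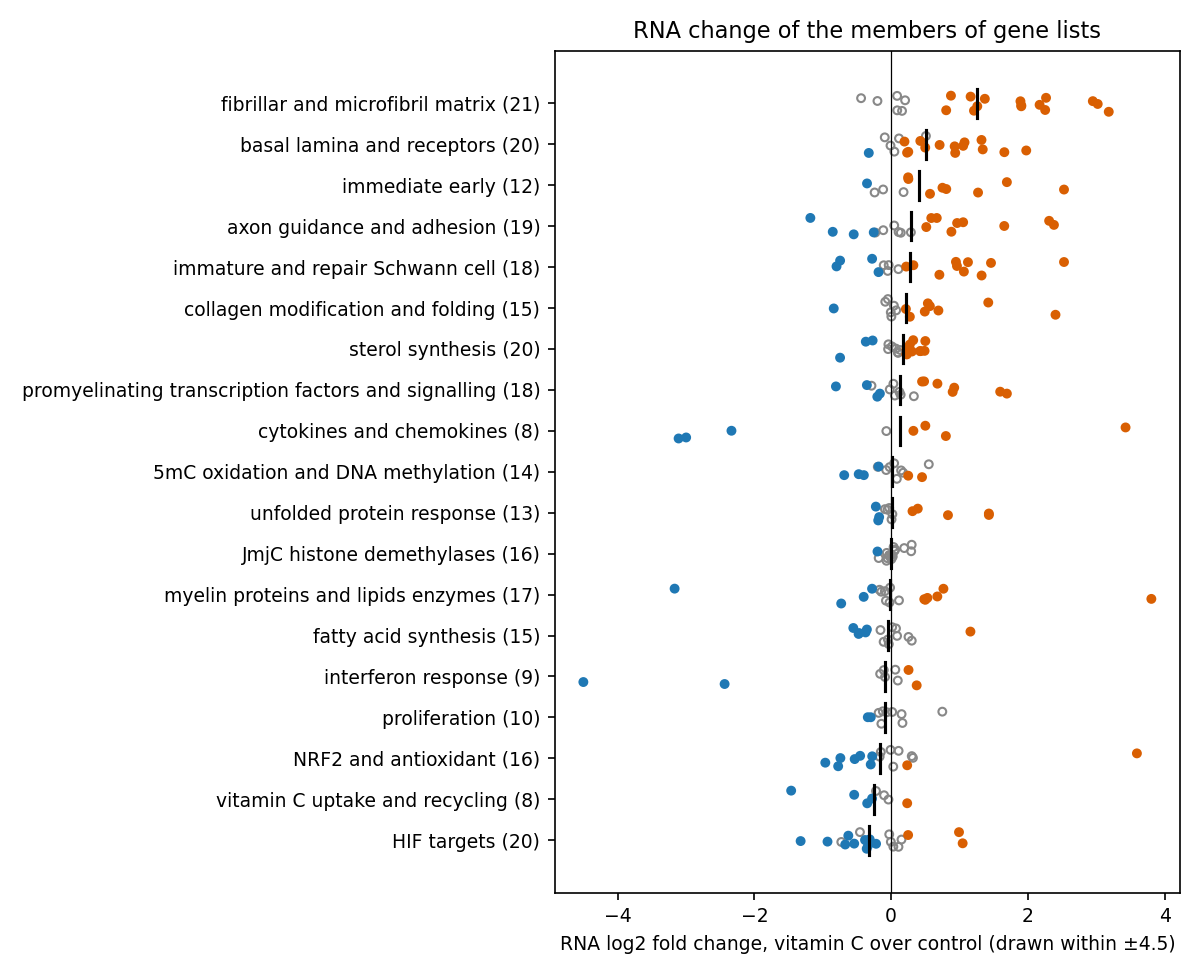
RNA log2 fold change, vitamin C over control, of the tested members of 19 gene lists, drawn within ±4.5, with the number of members in parentheses. Filled points passed the threshold (orange higher, blue lower), open points did not, and the bar marks the median, which is 1.26 for fibrillar and microfibril matrix and -0.32 for HIF targets.

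Among the largest changes in abundant genes outside these lists, Ldb2, a cofactor of LIM-domain transcription factors, rose by 4.07 ± 0.30, and the adhesion molecules Cadm2, Negr1 and Cadm3 rose by 3.16 ± 0.19, 2.80 ± 0.30 and 2.71 ± 0.17. The zinc transporter Slc39a12 fell by 3.91, the synaptotagmin Syt13 by 3.36 (from 134 ± 6.76 to 13.1 ± 0.919 CPM) and the netrin receptor Unc5d by 3.02. The matrix protein Spon1 fell by 2.89 and the signalling adaptor Sla by 2.56 (from 389 ± 12.8 to 65.7 ± 3.70 CPM). Of identifiers without a symbol, ENSRNOG00000020060 rose by 2.25 and ENSRNOG00000013306 by 2.18. ENSRNOG00000014117 fell by 2.42 and ENSRNOG00000057620 by 1.82. In all, 5188 of 12925 tested genes (40.1%) passed, 2473 higher and 2715 lower, 680 and 335 of them by more than 1 log2 unit. The groups did not overlap in 7076 genes (54.7%, where chance gives 10%). Vitamin C replicate 1 differed more from the other treated libraries (chi-square per degree of freedom 29.3 and 41.0) than they did from each other (5.54), and 5634 genes passed without it. Without control replicate 2, 3494 genes passed, 1710 higher and 1784 lower.

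In hMeDIP, a larger part of the counted reads lay in peaks in each treated library than in any control. Of all counted hMeDIP reads, 32.8 ± 2.61% lay in peaks in controls and 42.0 ± 1.63% with vitamin C (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest this design allows), against 8.57 ± 0.0813% and 8.53 ± 0.0891% of input reads. The ratio of hMeDIP to input reads in peaks, which is not scaled for the depth of either library, was 3.33 ± 0.148 in controls and 4.58 ± 0.158 in treated samples (exact permutation test, p = 0.1). Both measures depend on the peak list, whose calling and merging rule is not given in the sources used here. A list with more peaks called in treated libraries would by itself raise both there, so a gain over the whole genome is not shown.

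**Figure D3:**
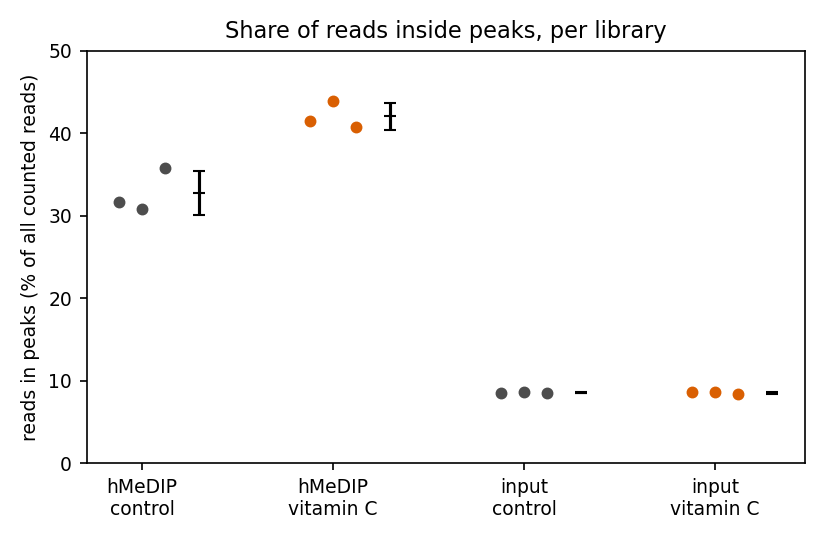
Percent of all counted reads that lie in peaks, for each hMeDIP and input library (points), with the mean and SD as a bar beside them. The treated hMeDIP libraries lie between 40.8% and 43.9% and the controls between 30.8% and 35.7%, and all input libraries between 8.43% and 8.65%.

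Relative to the average peak, gene bodies and promoters gained hMeDIP reads and regions far from genes lost them. Of peaks in gene bodies, 45.4% were higher and 29.8% lower with vitamin C, odds ratios of 1.76 (1.73 to 1.79) and 0.548 (0.538 to 0.558) against other peaks, with 95% intervals of Fisher's exact test. In gene deserts 69.0% were lower, an odds ratio of 3.75 (3.48 to 4.05), and 16.4% higher, and in other intergenic regions 44.9% were lower, an odds ratio of 1.80 (1.77 to 1.83), and 30.5% higher. When scaled by all counted reads, gene deserts stayed mostly lower (60.6%, against 29.8% higher), but other intergenic peaks were higher in 53.5% of cases and lower in 30.9%. Peaks labelled as proximal promoter, the smallest of 3 promoter classes, were higher in 48.1% of cases, an odds ratio of 1.54 (1.38 to 1.72), and lower in 24.4%. Peaks labelled Promoter1k were higher in 43.4% of cases and lower in 33.4%. Those labelled Promoter3k were higher in 43.1% and lower in 31.7%. The odds ratios for higher peaks were 1.28 and 1.27 in these 2 classes. On the X chromosome 371 of 2835 peaks were higher and 2101 lower, against 80995 and 79319 of 213023 on autosomes. The intervals treat peaks as independent, although all were counted in the same few libraries. Direction also followed a peak's place in the deposited list, as given below. Genomic features were not compared within the parts of that list, so the 2 patterns cannot be told apart.

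Single peaks moved in both directions, and those named here kept their direction when scaled by all counted reads. Positions are those of the peak list, whose genome build is not given in the sources used here. A peak in the body of Fgf5 (chromosome 14, 12982542 to 12990683) rose from 33.2 ± 1.43 to 69.0 ± 1.22 CPM (edgeR, adjusted p = 3.06e-29). Peaks in Pmepa1, an inhibitor of TGF-beta signalling (chromosome 3, 171304530 to 171314452), Fam78b (chromosome 13, 85202332 to 85206118), Cnksr3 (chromosome 1, 43872422 to 43881353) and Map4k4 (chromosome 9, 46715154 to 46719074) rose by 0.88, 1.26, 0.87 and 1.20. A peak near the promoter of Cdh13, a cadherin (chromosome 19, 51319509 to 51320234), fell from 12.1 ± 0.554 to 1.61 ± 0.261 CPM. Peaks in Cdkal1 (chromosome 17, 36971443 to 36972616), Iqcg (chromosome 11, 70986896 to 70987709) and Cdk5rap1 (chromosome 3, 149796083 to 149797477) fell by 1.92, 2.79 and 1.65. A peak labelled gene body at Prss23 (chromosome 1, 153731369 to 153732592), of which only the end overlaps the listed transcript, fell by 2.17. Of the best peaks of myelin genes, that in Cd9 (chromosome 4, 157994104 to 157997805) rose by 0.83 ± 0.05. Those in Sh3tc2 (chromosome 18, 57337555 to 57338437), Ugt8 (chromosome 2, 229655351 to 229655717) and Prx (chromosome 1, 84317578 to 84318344) fell by 1.58, 3.32 and 1.12. The peak in Fig4 (chromosome 20, 45980601 to 45982014) fell from 14.4 ± 0.756 to 7.18 ± 0.228 CPM. Counting all peaks of a gene, 18 of 35 at Mbp were higher and 5 lower, 11 and 3 of 18 at Pmp22, and 2 and 1 of 3 at Egr2.

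Of 308 peaks at 18 promyelinating genes, 217 were higher and 38 lower (219 and 38 adjusted over the list alone; camera in limma, adjusted p = 1.81e-11, and adjusted p = 0.0944 with an estimated correlation). Of 190 peaks at genes of immature and repair cells, 125 were higher and 26 lower (125 and 27 adjusted over the list alone; adjusted p = 1.81e-11 in limma's camera, and adjusted p = 0.112 with an estimated correlation). Of 184 peaks at myelin genes, 87 were higher and 47 lower, the same adjusted over the list alone (camera in limma, adjusted p = 0.0641, and 0.0457 to 0.0772 over left-out libraries), and the list passed without vitamin C replicate 3. Other lists also passed upwards, with adjusted p = 0.112 to 0.247 with an estimated correlation. Higher and lower peaks numbered 64 and 13 of 93 at sterol synthesis genes, 285 and 94 of 491 at basal lamina genes (286 and 95 adjusted over the list alone) and 46 and 13 of 75 at Schwann markers. They numbered 151 and 84 of 298 at fibrillar matrix genes, 58 and 21 of 111 at HIF targets, 74 and 38 of 154 at collagen modification genes and 20 and 8 of 31 at immediate early genes. Adjusted over the list alone, the counts were the same except for basal lamina. The call of collagen modification (adjusted p = 0.0491 in limma's camera, and 0.0423 to 0.0661 over left-out libraries) was lost without control replicate 1 or 2 or vitamin C replicate 2, and that of immediate early genes (adjusted p = 0.0491 in limma's camera, and 0.0361 to 0.0628 over left-out libraries) without control replicate 2 or 3 or vitamin C replicate 1 or 2. Both calls were also lost with the replicate block (adjusted p = 0.0542 in limma's camera for each list). Macrophage markers passed downwards, with 3 of 36 peaks higher and 20 lower (3 and 20 adjusted over the list alone; adjusted p = 0.0423 in limma's camera, and adjusted p = 0.247 with an estimated correlation). For fibroblast, perineurial, endothelial, pericyte and neuron markers, none of them past the threshold, the median, mean and direction of the test differed in sign. Of the 10 lists that passed, 0 did so with an estimated correlation (5 at an unadjusted p under 0.05), and peaks with any gene had a higher median change (0.16) than peaks without one (-0.11). Camera compared each list with all peaks, with or without a gene. Of peaks with any gene, 45.1% were higher and 30.1% lower. The share of higher peaks was 47.3% at myelin genes. In lists that passed upwards it ran from 48.1% (collagen modification) to 70.5% (promyelinating genes).

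In all, 162865 of 215951 peaks (75.4%) passed in edgeR, 81381 higher and 81484 lower, and 5937 and 34713 of them changed by more than 1 log2 unit. Libraries of a group differed little beyond sampling noise over peaks, so these calls are not shown to allow for spread between cultures. The split into higher and lower peaks depended on the scale. Scaling by all counted reads gave 131502 higher and 52887 lower and moved the median change from 0.04 to 0.47. Scaling by input reads in peaks, which keeps differences in sequencing depth, gave 142453 and 49156 and a median of 0.57. The direction of a peak also followed its place in the deposited list, which runs through the chromosomes more than once. It was divided, after the data were seen and only approximately, where chromosome 11 recurs. Of the 67116 peaks before that point, 88.2% were lower. Of the 148835 later ones, 53.3% were higher and 15.0% lower. Input DNA, tested over 215759 of the same peaks, gave 0 calls in edgeR (10477 at an unadjusted p under 0.05) and 0 in DESeq2 (1556 unadjusted). The change of hMeDIP relative to input passed in edgeR at 108702 peaks, 47316 higher and 61386 lower (101863 and 35185 when scaled by all counted reads). Of 106957 peaks called in both tests 106956 had the same sign. Both tests used the same hMeDIP libraries and input changed little (median -0.0018), so this agreement was largely fixed in advance.

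**Figure D4:**
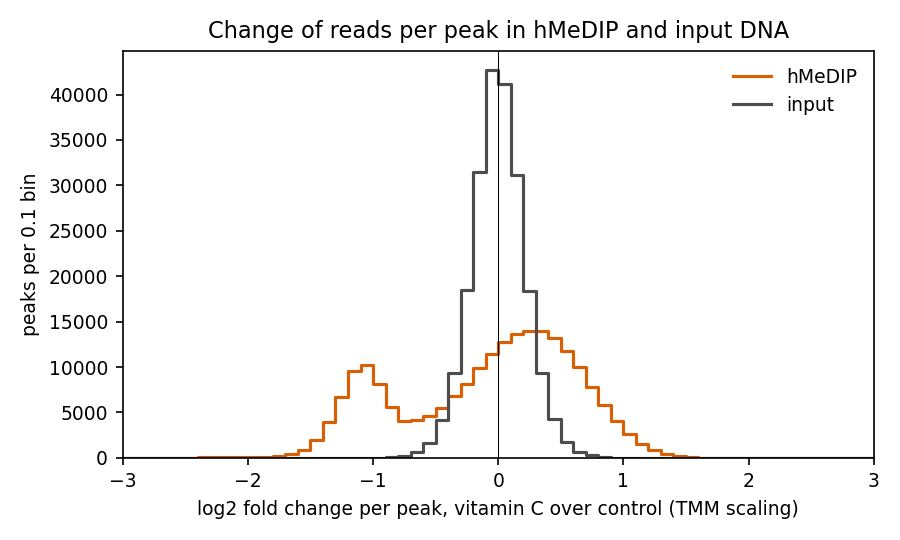
Number of peaks per 0.1 bin of log2 fold change, vitamin C over control with TMM scaling, for hMeDIP (orange) and input (grey). Changes in hMeDIP form a broad group above 0 and a narrower one near -1, the median of the lower peaks being -0.93, while input changes centre on a median of -0.0018.

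Genes higher in RNA held hMeDIP peaks of either direction of change more often than other genes did, and genes lower in RNA held both less often. The integrin gene Itgb4 rose in RNA and had 5 of 8 peaks higher and 0 lower, and Sla fell in RNA and had 0 of 13 peaks higher and 8 lower. Adamts2, which rose in RNA, had 21 of 37 peaks higher and 7 lower, Nrp2, which also rose, had 16 and 11 of 37, and Spon1, which fell, had 25 and 20 of 63. Of genes higher in RNA, 87.1% held a higher peak against 76.7% of other genes (Fisher's exact test, odds ratio 2.05, 1.79 to 2.35), and 76.1% held a lower peak against 65.5% (1.68, 1.51 to 1.88). Of genes lower in RNA, 74.3% held a higher peak against 80.3% (0.708, 0.631 to 0.794), and 63.3% a lower peak against 69.1% (0.772, 0.696 to 0.856). A gene counted if any of its peaks was called, and the number of peaks per gene was not allowed for. Differing peak numbers alone could therefore raise or lower both shares together. Across 10021 genes, which are not independent replicates, the RNA change and the mean hMeDIP change had a Spearman rho of 0.0256 (permutation p = 0.0103). The correlation was -0.0493 when each gene took its peak of smallest p (permutation p = 1e-05, the smallest the permutations can give). It was 0.0744 with promoter peaks alone (permutation p = 1e-05, the smallest possible) and 0.00835 with gene body peaks alone (permutation p = 0.441). Within strata of peak number and RNA level it had a permutation p = 0.139. Without control replicate 3 or vitamin C replicate 3 the rho was 0.0189 in both cases (permutation p = 0.0568 and 0.0575).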

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

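Scaling by all counted reads, the share of all counted reads, the match on mean expression and the 2 against 2 fit were chosen after the data were seen. Of 128 RNA changes of named genes, none changed direction under library-size scaling, DESeq2, the replicate block or leaving out a library. Calls were lost in at least 1 of these for Aurka, Erbb3, Gap43, Ifi44, Ifit2, Jun, Kdm2b, Mbd2, Mef2c and Tet3 and gained for Sox10, and the causes were not tested. The 26 named peaks kept their calls and directions in the same settings. Total counts of called genes and peaks stayed within 1.5 times those given in the report in every setting run, but counts per direction did not. Scaling by all counted reads or by input reads moved both hMeDIP counts further (131502 higher and 52887 lower, and 142453 and 49156), as did all counted reads for hMeDIP relative to input (101863 and 35185), and 1784 RNA genes were lower without control replicate 2. RNA gave 3494 (without control replicate 2) to 5634 (without vitamin C replicate 1) genes over left-out libraries and 4672 in DESeq2. For hMeDIP the counts were 153487 to 159902 peaks over left-out libraries, 139061 in DESeq2 and 158065 with replicates 1 and 3 of each group summed. Relative to input they were 93963 to 102871 peaks. Dropping the filter removed no hMeDIP peak and tested nothing there. Replicate numbers did not pair the samples consistently. In RNA the replicate 1 libraries of both groups correlated best with each other, while in hMeDIP no library correlated best with its own number. Same-numbered RNA libraries deviated together with r = 0.17, 0.05 and 0.01 and hMeDIP libraries with -0.03, -0.20 and -0.11, and not every library correlated best with its own number. With the replicate block 5544 RNA genes and 158904 hMeDIP peaks passed, and 8 RNA lists and 8 hMeDIP lists. With it the promyelinating RNA list passed (adjusted p = 0.0368 in limma's camera), and the calls of Ifi44 in RNA and of the collagen modification and immediate early lists in hMeDIP were lost (adjusted p = 0.0542 in limma's camera for each list). Of 7 RNA lists past the threshold 2 passed with an estimated correlation, whereas fry, which does not compare a list with other genes, called 19. Against lists matched on mean expression 8 RNA lists passed, HIF targets (adjusted p = 0.0024) and fibroblast markers (0.0234) being gained and collagen modification (0.060) lost. The matched lists do not allow for correlation between genes. Of 10 hMeDIP lists 0 passed with an estimated correlation (5 at an unadjusted p under 0.05), and 8 to 14 lists passed at the preset correlation over left-out libraries. Without vitamin C replicate 3 the lists gained were cytosine oxidation, fatty acid synthesis, myelin and unfolded protein response. Some lists that were not called changed direction in limma's camera. These were JmjC demethylases without vitamin C replicate 3 (adjusted p = 0.955, and 0.678 to 0.975 over left-out libraries), neuron markers without vitamin C replicate 1 (0.875; 0.669 to 0.875) and perineurial markers with the replicate block (0.712) and without control replicates 1 and 2 (0.827 and 0.869; 0.220 to 0.869). The cause was not tested. The correlation of RNA and hMeDIP changes changed most with the setting. It turned to -0.0493 with the peak of smallest p, was 0.00835 for gene body peaks, kept its 0.0256 without passing within strata, and ranged from 0.0189 to 0.0463 over left-out libraries; the cause was not tested. The difference in the ratio of hMeDIP to input reads in peaks kept its sign in every setting (1.17 to 1.33 over left-out samples), in a design where no p below 0.1 can occur. Of simulated changes of 0.5 log2 units, 7.46% were recovered in input and 73.1% in hMeDIP, which has more reads in peaks, though depth itself was not varied.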

Other observations

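The 4 gene lists in this part were written after the RNA values had been seen, and leave out the genes that prompted them; for Sesn2, Ddit3, Gadd45a and Sox10, which also belong to lists fixed earlier, the values were already known. The examples named from them were chosen after their values were seen. The tests of dilution, of the parts of the peak list and of X peaks within those parts were also chosen after their values were seen.

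Genes that respond to amino acid shortage through the transcription factor ATF4 rose together. Of 26 tested targets, 21 rose and 0 fell, with a median change of 0.54 (camera in limma, p = 2.25e-13, and p = 0.0331 with an estimated correlation). Among them were Psat1, an enzyme of serine synthesis (1.13 ± 0.05), Mthfd2, a mitochondrial folate enzyme (1.35 ± 0.06), and the arginine transporter Slc7a1 (1.52 ± 0.10). Of 23 targets of YAP and TEAD, factors that respond to cell stretch and contact, 13 rose and 4 fell, with a median of 0.53 (camera in limma, p = 8.12e-05, and p = 0.0121 with an estimated correlation). Ctgf rose by 1.55 ± 0.09 and Ankrd1 by 1.60 ± 0.12. The melanocyte-related genes Kit, Gpnmb, Oca2 and Pmel fell by 2.13, 1.75, 1.53 and 1.84, but of 10 other pigment cell genes 3 rose and 3 fell. The median of these others was 0.0732 (camera in limma, p = 0.949, and p = 0.950 with an estimated correlation).

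Skeletal muscle genes rose together. Of 37 tested, 33 rose (89.2%) and 0 fell, with a median of 1.60 (camera in limma, p = 1.10e-23, and p = 0.0147 with an estimated correlation). The most abundant were Mef2c (from 265 ± 18.2 to 326 ± 43.3 CPM, a call lost under library-size scaling and on leaving out any 1 control or vitamin C replicate 2), Acta1 (from 35.4 ± 5.58 to 110.0 ± 5.02 CPM) and Myl1 (from 25.8 ± 4.47 to 87.0 ± 6.99 CPM), with the embryonic myosin Myh3 (from 100.1 ± 21.7 to 344 ± 11.5 CPM) among the prompting genes, while the regulator Myod1 was at a lower level (from 2.24 ± 0.366 to 4.64 ± 0.134 CPM). A single treated library carrying muscle RNA is argued against, since in 100% of the called genes all 3 treated libraries lay above all 3 controls. More, or more mature, muscle-lineage cells in the treated cultures remain a candidate explanation, and the labels name no sort that would remove such cells. Expression of these genes by the Schwann cells themselves was not tested and stays open.

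The lower hMeDIP peaks, 81484 with a median change of -0.93, may have technical causes. Peaks picked between the replicate 1 libraries alone had a median of -0.93 in replicates 2 and 3. That argues against sampling noise of reads in picking them. Since replicates 1 and 3 differed by no more than such noise, it does not address variation between cultures. A difference in the DNA is also argued against, since the median input change at the lower peaks was 0.0222. Dilution of an unchanged background by reads gained elsewhere stays open. On the scale of all counted reads the median of the lower peaks lay below the change of reads outside peaks in all 9 pairs of libraries, by -0.40 to -0.102. That last value passed a bound of -0.1, set after the values were seen, by little. The peaks were picked as lower in the same libraries, which favours that outcome, so the comparison cannot decide. How the merged list was put together stays open: the share of lower peaks was 73.3 points larger in its first part, which peaks called apart in each group could give, and the merging rule is not given in the sources used here. A difference between immunoprecipitation batches cannot be told apart from an effect of vitamin C, which was itself not tested further, since the labels name no batch.

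The X chromosome held mostly lower hMeDIP peaks, with a median of -0.57 against 0.47 on autosomes on the scale of all counted reads. Less X DNA in the treated cultures is argued against, since the X share of input peak reads changed by 0.0251 on the log2 scale. Autosomal peaks matched on control enrichment, width and feature had a median of -0.09, so X peaks lay at -0.48 relative to them, beyond a bound of -0.3 set beforehand. That bound did not allow for the parts of the peak list, and is set aside for that reason: 68.5% of X peaks but 30.6% of autosomal ones lay in the first part, and within the parts X and autosomal medians differed by at most -0.13 (-0.70 against -0.56, and 0.60 against 0.71). The X pattern may therefore be the pattern of the lower peaks seen again, and the 2 cannot be told apart while the origin of the parts is open.

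Regrouping the 6 libraries of an assay gives 10 splits, too few for a share under 0.05. In RNA 1 of the 10 splits, the real one, gave 5188 genes and the highest other gave 0; in hMeDIP 1 gave 162865 peaks and the highest other 0; in hMeDIP relative to input 1 gave 108702 peaks and the highest other 0. In input the real split gave 0 calls in edgeR (10477 at an unadjusted p under 0.05, and 0 in DESeq2), all 10 splits gave at least as many, and the highest other gave 6.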
